A study of Mus musculus with 8 samples.

How the data were processed

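Gene expression was measured on 8 single-colour Agilent arrays of Cy3-labelled RNA from samples whose source was given as astrocytes and whose tissue label was spinal cord, from C57Bl/6J mice. Each array was the only 1 of its group. The groups were wild-type (WT) or connexin 47 (Cx47) deficient mice, each naive, with experimental autoimmune encephalomyelitis (EAE), with EAE and iguratimod, and with chronic EAE. The sample titles mark the mice called WT here as FL or F/F and the Cx47-deficient mice as icKO. For the naive arrays the genotype was taken from these titles, which were not interpreted further. Per the labels' protocols, RNA was extracted with TRIzol and a column kit and amplified with a low-input labelling kit. How the cells were isolated was not given in the sources used here. Nothing in the labels states that the arrays carried samples of separate animals, so the p-values of the gene fits measure only the spread between these arrays. With 1 array per group, the spread left in a fit is how far the genotype difference varied between conditions. That spread may be technical.

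The deposited scanner files hold spot intensity values, per the file headers from Agilent Feature Extraction 10.7.1.1. Per the submitters' processing notes the version was 9.5.1.1, and this difference was not resolved. Per the file headers each array held 62976 spots, 59305 of them not control spots, read in 1 channel, with probe positions on the mm9 build. The signal used was the processed signal, an intensity from which the scanner software had subtracted background and spatial trend, per the file headers. A table of the authors' processed values was also deposited. Its unit was worked out from the values: intensity on a linear scale, quantile normalized between arrays, with a median of 50.2 in each of the 8 columns, values between 2.96 and 361676, and no centring of genes; they are intensities of single arrays and not ratios, so no direction between groups is built in. It served only as an alternative. Flags of 0 or 1 and other columns per spot were taken as deposited. There were 0 columns of values per sample that could not be assigned to a sample.

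Arrays fell on 2 slides, each scanned in a session of its own: 6 arrays on slide 1 and the 2 chronic arrays on slide 2. The processed signal was put on a log2 scale, and each array's percentile 75 was subtracted. Spots marked as outliers, between 38 and 73 per array, were left out, and spots of the same probe were averaged. A probe was kept when it was well above background on at least 2 of the 8 arrays, and a gene was represented by its kept probe with the highest mean signal. This left 25884 genes, of which 8794 had several kept probes. Of 56605 probes, 32994 were named through an accession in a RefSeq gene table, 10224 through a symbol and 520 through a synonym, and 12867 kept the name in the file, so a few names are those of the array design.

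Comparisons over both genotypes or all conditions were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as condition plus genotype over all 8 arrays, with 3 residual degrees of freedom, 2.14 prior degrees of freedom and a prior SD of 0.235 on the log2 scale. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The fit assumes the same genotype effect in every condition. Differences between single arrays have no replicate, were not tested, and are counted at 2-fold or more among genes well above background on at least 1 of the arrays compared, with a dim value raised to the lowest signal among probes well above background on its array. Where a gene was not well above background on any array of a group, its ratio is given as at least N-fold, from the other group's mean over all its arrays against the mean of the higher of each dim array's floor and the dim probe's own signal.

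The 34 gene lists of cell types, reactive states and pathways, the comparisons, the tests and nearly all alternatives were fixed before the data were examined. In the fits they were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list's members with the other genes. Its p-values at the preset correlation therefore rest largely on the spread over genes and not between arrays. Fry asks whether members move on balance one way and does not compare them with other genes. Between single arrays a list's median is given as a percentile among 10000 random lists of the same size matched on mean expression, which describes these arrays only. The genes named were chosen by a rule: in each fit the 8 largest rises and the 8 largest falls among called genes with the same sign in every matched pair; in each genotype and iguratimod difference between single arrays the 6 largest on each side that were also 2-fold after normexp background correction; up to 4 members with the largest difference in each list discussed; and always Gfap, Gja1, Gjb6 and Il6. Some genes that the rule names are not reported. Names of unnamed clones of certain kinds were passed over in the ranked part.

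The fit and the list tests were tested on simulated data whose spread was drawn from the prior fitted to these arrays. In simulations of the genotype effect over 25884 genes, 0% of genes changed 2-fold, 71.8% of those changed 4-fold, 89.2% of those changed 8-fold and 93.7% of those changed 16-fold were recovered. In simulations of EAE against naive the shares were 0%, 11.3%, 73% and 86.3%. The alternatives were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization alone, median centring, the authors' processed values, other filters on dim probes, the mean of a gene's probes, trended and robust moderation, other blocks, slide 1 only, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.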

Results

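Experimental autoimmune encephalomyelitis is the mouse model of multiple sclerosis, and Cx47 is a gap junction protein of oligodendrocytes that couples them to astrocytes. RNA described as astrocytic was profiled on 8 arrays, 1 for each combination of genotype (WT or Cx47-deficient) and condition (naive, EAE, EAE with the anti-inflammatory compound iguratimod, or chronic EAE). The series names the naive array as its control. Between 59.7% and 72.0% of spots were well above background on an array. The 2 chronic arrays lay on a slide of their own, with 72.0% and 71.3% of spots well above background, a median local background of 57 and 58, and a spike-in slope of 0.76. On the other 6 arrays the background was 73 to 82 and the slope 0.92 to 1.07. The R squared of the spike-in line was 0.848 and 0.846 on the chronic arrays and 0.964 to 0.988 on the others. The number of arrays limits the precision of every comparison.

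**Figure D1:**
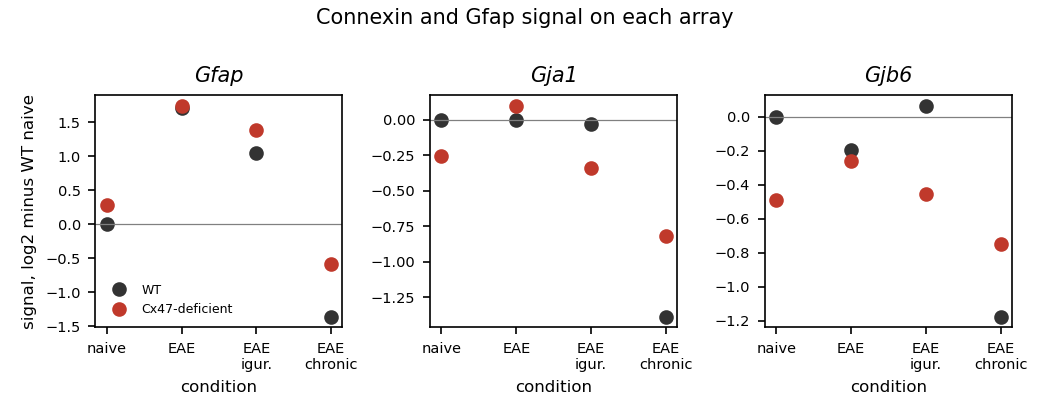
Signal of Gfap, Gja1 and Gjb6 on each of the 8 arrays, as log2 minus the WT naive array on the vertical axes, by condition on the horizontal axes; each point is 1 array, dark for WT and red for Cx47-deficient. Gfap was above WT naive on all EAE and iguratimod arrays and below it on both chronic arrays.

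Whether Cx47 deficiency altered expression regardless of condition was asked over the 4 matched pairs. Larger fitted differences among the named genes lay in immune genes: the B cell chemoattractant Cxcl13 (1.71 ± 0.57), the macrophage lectin Chil3 (1.64 ± 0.75), the T cell adhesion molecule Cd2 (1.17 ± 0.41), Cd74 (0.90 ± 0.25), Cxcl10 (0.87 ± 0.14) and complement C3 (0.83 ± 0.21), all higher in the Cx47-deficient mice as log2 values with SE. None of these passed the test. Cxcl13 was well above background on 3 of the 4 Cx47-deficient and 2 of the 4 WT arrays, Cd2 on 3 of 4 and 3 of 4, and Cxcl10 on 4 of 4 and 3 of 4. The astrocyte genes differed less: Gfap by 0.35 ± 0.16, Gja1, which encodes connexin 43, by 0.03 ± 0.19, and Gjb6, which encodes connexin 30, by -0.16 ± 0.20. Il6 differed by 0.26 ± 0.57 and was well above background on 2 of the 4 Cx47-deficient and 1 of the 4 WT arrays. The sign for Gja1 turned with median centring (-0.01) and without WT chronic, without Cx47-deficient chronic and on slide 1 alone (each -0.15), and that for Il6 without WT iguratimod or Cx47-deficient iguratimod (each -0.39).

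Over all 25884 genes, limma called 0 for genotype. At an unadjusted p under 0.05 there were 1143, of which 853 were higher and 290 lower in Cx47-deficient mice, against 1294 that chance would give. Genotype differences that vary between conditions count as spread in this fit. A count under that of chance therefore does not show that genotype had no effect. Of the 34 lists, camera called 11 higher and 3 lower, and fry called 0. The lower calls depended on the processing: camera called 11 higher and 0 lower under quantile normalization, with the authors' values and with no filter, 10 higher and 1 lower with the mean of probes, and 2 or 3 lower under normexp, median centring and the filter on all arrays. The complement list had a median of 0.44, with 12 of 12 members above 0 (camera adjusted p 0.000498; adjusted p = 0.858 with an estimated correlation). The interferon-stimulated list had a median of 0.43, with 16 of 17 above 0 (camera adjusted p 0.000498; adjusted p = 0.858 with an estimated correlation). The pan-myeloid list had a median of 0.40, with 12 of 13 above 0 (camera adjusted p 0.000498; adjusted p = 0.858 with an estimated correlation). T and NK cell genes had the highest median of the 34 lists, 0.62, with 11 of 13 above 0 (camera adjusted p 0.00352; adjusted p = 0.858 with an estimated correlation). B and plasma cell genes had a median of 0.48, with 6 of 6 above 0 (camera adjusted p 0.00935; adjusted p = 0.858 with an estimated correlation), and monocyte and macrophage genes 0.25, with 10 of 13 above 0 (camera adjusted p 0.0302; adjusted p = 0.858 with an estimated correlation). The other higher calls were MHC class II presentation (median 0.46), chemokines (0.43), A1 reactive astrocyte genes (0.36), MHC class I (0.30) and pan-reactive astrocyte genes (0.27), each with adjusted p = 0.858 with an estimated correlation. These medians pool unlike pairs. Complement genes were at -0.07 in the naive pair, 0.48 in EAE, 1.17 with iguratimod and 0.18 in chronic EAE. Interferon-stimulated genes were at -0.53, 0.30, 1.19 and 0.45 in the same order, and T and NK cell genes at -0.13, 0.79, 1.58 and 0.11. Cholesterol synthesis genes had a median of -0.17, with 2 of 16 above 0 (camera adjusted p 0.0164; adjusted p = 0.892 with an estimated correlation). Their camera adjusted p was 0.109 under quantile normalization, 0.107 with the authors' values, 0.130 with no filter and 0.153 with the mean of probes, and under 0.05 in the other alternatives run. None of the list calls held with an estimated correlation. That setting called 0 lists in every fit, EAE against naive included, so failing it does not tell one list from another. On the 6 arrays of slide 1 alone, an alternative for the lists chosen after seeing the data, camera called 14 lists, 9 higher and 5 lower.

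In the naive pair, the genes lower in the Cx47-deficient mouse included receptors of striatal neurons. The adenosine receptor Adora2a, a gene of striatal neurons, was at least 61.1-fold lower in the Cx47-deficient mouse, and Gpr6, another receptor of striatal neurons, was lower by a log2 difference of -3.93. Ido1, an enzyme of tryptophan breakdown, differed by -4.05, Lrrc10b by -3.54 and Htr5b by -3.50. On the higher side stood the phosphatase gene Ptpn22 (3.08), the matrix gene Ltbp2 (3.04), Cnpy1 (2.97) and 3 unnamed transcripts, BM934532 (3.38), AK042933 (3.31) and BY643365 (3.12). Vessel genes were lower: the endothelial list had a median of -1.13, below all 10000 matched random lists (percentile 0), with Ly6c1 at -1.68, Slco1a4 at -1.53 and the tight junction gene Cldn5 at -1.26. The ependymal list had a median of -0.84 (percentile 0.01) and the interferon-stimulated list a median of -0.53 (percentile 0). The erythroid list had a median of 1.03 (percentile 99.98). Gfap differed by 0.29, Gja1 by -0.25 (0.31 with the mean of its probes) and Gjb6 by -0.49, and Il6 was not well above background on either array. Of the 23311 genes compared, 1915 were higher and 633 lower by 2-fold or more, so 75.2% were higher. Under quantile normalization 1348 were higher and 1149 lower, and the share was 54.0%; with the authors' processed values it was 54.4%.

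In the EAE pair, immune genes were higher in the Cx47-deficient mouse. The macrophage lectin Chil3 differed by 3.78, the chemokine Cxcl13 by 2.06, the T cell gene Cd2 by 1.57, the reactive astrocyte gene Lcn2 by 1.56, macrophage lysozyme Lyz2 by 1.43, complement factor Cfb by 1.27 and Ccl5 by 1.27. The T and NK cell list had a median of 0.79 (percentile 99.8), the neutrophil list 0.83 (percentile 99.8), the monocyte and macrophage list 0.71 (percentile 99.7) and MHC class II presentation 0.74 (percentile 99.98). Myelin genes were lower, with a median of -0.38 (percentile 0.01), Opalin at -1.18 and Mobp at -1.01, and so were cholesterol synthesis genes, with a median of -0.39 (percentile 0). Beside these, a list of cerebellar neuron genes drawn up later had a median of 1.98 (percentile 100), with 8 of 9 members higher by 2-fold. Other large differences were at least 14.1-fold for Oxct2b, 12.3-fold for Dsg1c, 12.1-fold for Kif12 and 11.3-fold for Adamtsl3, each dim on the WT array. On the lower side were Pde5a (-2.69), Omp (-2.15) and Hoxc8 (-2.14). Gfap differed by 0.03, with the sign turned under median centring (-0.01), Gja1 by 0.10 and Gjb6 by -0.07, which turned under normexp (0.05), quantile normalization (0.07), the authors' values (0.07) and the mean of probes (0.09). The dim Il6 signal on the WT array allowed a log2 difference of at least 0.26. Of 23591 genes, 1575 were higher and 164 lower by 2-fold, or 90.6% higher. The counts were 925 and 434 under quantile normalization, or 68.1% higher, and 69.2% were higher with the authors' values.

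In the iguratimod pair, lymphocyte, antigen presentation and interferon-stimulated genes were higher in the Cx47-deficient mouse. Cxcl13 differed by 2.99, the lymphocyte GTPase Gimap3 by 2.66, the interleukin 2 receptor Il2rb by 2.58, the dendritic cell integrin Itgax by 2.41, Cd2 by 2.32, Cd3g by 2.26 and the chemokines Ccl3 and Ccl5 by 2.08 and 1.80. The list medians were 1.58 for T and NK cells, 1.31 for MHC class II, 1.19 for interferon-stimulated genes, 1.17 for complement and 1.06 for MHC class I, each above all matched random lists (percentile 100). The neutrophil list went the other way, with a median of -0.52 (percentile 0.11), as did the erythroid list with -1.37 (percentile 0). The striatal dopamine receptor Drd1 and Gpr6 were higher by 2.45 and 2.42, and the later list of cerebellar neuron genes had a median of -1.31 (percentile 0). On the lower side were Prl2c5 (-2.51), Ssty1 (-2.40) and the folate receptor Folr1 (-2.28). Gfap differed by 0.33, Gja1 by -0.31 (0.33 with the mean of its probes) and Gjb6 by -0.52; Il6 was dim on the WT array, which allowed a difference of at least 0.27. In all, 592 genes were higher and 524 lower by 2-fold, or 53.0% higher. The balance turned under quantile normalization, with 445 and 527 (45.8% higher), with the authors' values, with 431 and 508 (45.9%), and at 3-fold, with 75 and 128 (36.9%).

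In the chronic pair, the astrocyte, myelin and endothelial lists had higher medians in the Cx47-deficient mouse. Larger single differences lay in genes outside these lists. The alarmin receptor Ager differed by 4.80, the thyroxine carrier Ttr by 2.84, the channel subunit Kcne2 by 2.31, and the water channel Aqp1 by 2.07. Astrocyte markers had a median of 0.71 (percentile 100), with Fabp7 at 1.16, Aqp4 at 1.15, S100b at 1.07 and Gfap at 0.77. Gja1 differed by 0.56 and Gjb6 by 0.43. The endothelial list had a median of 0.91, the erythroid list 1.56, the ependymal list 0.74 and myelin genes 0.46, each at percentile 100. Lower were Chchd4 (-6.57), the neutrophil protein Ltf (-4.36), the keratin Krt14 (-4.01) and Plet1 (-3.90). The platelet chemokine Ppbp was at least 22.7-fold lower and the hormone gene Avp at least 17.0-fold lower. Il1b differed by -2.12, and Il6 was lower by at least 0.64 on the log2 scale, being dim on the Cx47-deficient array (log2 difference -0.64). In all, 419 genes were higher and 330 lower by 2-fold, or 55.9% higher, and under normexp 80 and 85, or 48.5% higher.

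EAE was compared with naive over both genotypes to see how disease altered the profile. Genes of the chemokine, antigen presentation, complement and reactive astrocyte lists rose. These lists share members, so their calls are not independent. The A1 list holds H2-T23, H2-D1 and Psmb8 of the MHC class I list and Serping1 of the complement list. The pan-reactive list holds Cxcl10 of the chemokines. Which cells carried a rise was not measured. Cxcl10, an interferon-induced chemokine that attracts T cells, rose 119.6-fold (log2 6.90 ± 0.20, adjusted p 0.00668; well above background on 1 of 2 naive arrays). Cxcl9 rose at least 43.9-fold (adjusted p 0.0283), complement factor Cfb at least 47.1-fold (0.0373), Plac8 at least 54.3-fold (0.0338), Ms4a15 at least 70.3-fold (0.0277) and Ccl8 at least 33.5-fold (0.0373), all dim on both naive arrays. Ccl5 rose 107.1-fold and the interferon-inducible GTPase Iigp1 87.4-fold, both with an adjusted p of 0.0277. Acot12 was the only gene that fell, by at least 1.02-fold, with an adjusted p of 0.0421, dim on both EAE arrays and measured on 1 of 2 naive arrays.

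Of 7 MHC class II genes, 4 rose: H2-Aa 69.2-fold, H2-Ab1 61.6-fold, H2-Eb1 42.2-fold and the invariant chain Cd74 35.6-fold. Adjusted over the list alone, 6 rose (camera adjusted p 9.3e-14; adjusted p = 0.106 with an estimated correlation). Of 16 chemokines 7 rose, and 14 when adjusted over the list alone (camera adjusted p 2.79e-26; adjusted p = 0.102 with an estimated correlation). Of 12 pan-reactive astrocyte genes, the iron-binding Lcn2 (49.2-fold), Timp1 (8.08-fold) and Cxcl10 rose, and 10 when adjusted over the list alone (camera adjusted p 2.43e-20; adjusted p = 0.0913 with an estimated correlation). Gbp2 and Iigp1 rose among 11 A1 reactive genes, Gbp2 by 45.6-fold, and 8 when adjusted over the list alone (camera adjusted p 8.85e-20; adjusted p = 0.116 with an estimated correlation). The A2 gene Tgm1 rose at least 3.61-fold. C3 rose 16.03-fold, and adjusted over the list alone 11 of 12 complement genes rose (camera adjusted p 1.96e-20; adjusted p = 0.107 with an estimated correlation). The NF-kB targets Bcl3 and Icam1 rose 11.8-fold and 5.76-fold, and the neutrophil protein S100a9 9.73-fold. None of the 17 interferon-stimulated genes passed over all genes, while 15 rose when adjusted over the list alone, and their median was 3.11 (camera adjusted p 4.2e-26; adjusted p = 0.116 with an estimated correlation). Gfap differed by 1.59 ± 0.22 (adjusted p 0.0813).

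Markers of infiltrating and vessel cells moved with these groups. The monocyte and macrophage list had a median of 2.86 (camera adjusted p 9.18e-22; adjusted p = 0.0977 with an estimated correlation), T and NK cells 2.42 (camera adjusted p 2.27e-16; adjusted p = 0.125 with an estimated correlation), neutrophils 2.28 (camera adjusted p 6.6e-14; adjusted p = 0.106 with an estimated correlation) and endothelial cells 2.41 (camera adjusted p 1.93e-14; adjusted p = 0.142 with an estimated correlation). Myelin genes had a median of -0.56, with none past the test (camera adjusted p 6.17e-06; adjusted p = 0.421 with an estimated correlation). The general astrocyte list had a median of 0.02 (camera adjusted p 0.512), with Gja1 at 0.18 ± 0.26 and Gjb6 at 0.02 ± 0.28. Averaging the probes of a gene turned both (-0.19 and -0.11), and so did leaving out the Cx47-deficient naive array (-0.01 and -0.20); without the Cx47-deficient EAE array Gjb6 was at -0.05. Il6, dim on both naive arrays and on 1 of 2 EAE arrays, was at least 1.06-fold higher (adjusted p 0.879).

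In all, limma called 65 genes, 64 higher and 1 lower in EAE, all with the same sign in both genotypes. Camera called 19 lists higher and 2 lower, fry called 16, and no call held with an estimated correlation. Leaving out any of the 8 arrays lost most of these calls, and the 6 arrays of slide 1 alone gave 0 calls. All 65 genes kept their sign in each of these fits. The fits reuse the arrays on which the 65 genes were chosen, so this adds no support. On slide 1 alone camera called 21 lists. In the single genotypes, without a test, 754 genes were higher and 431 lower by 2-fold in WT, and 1237 higher and 518 lower in the Cx47-deficient mice.

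**Figure D2:**
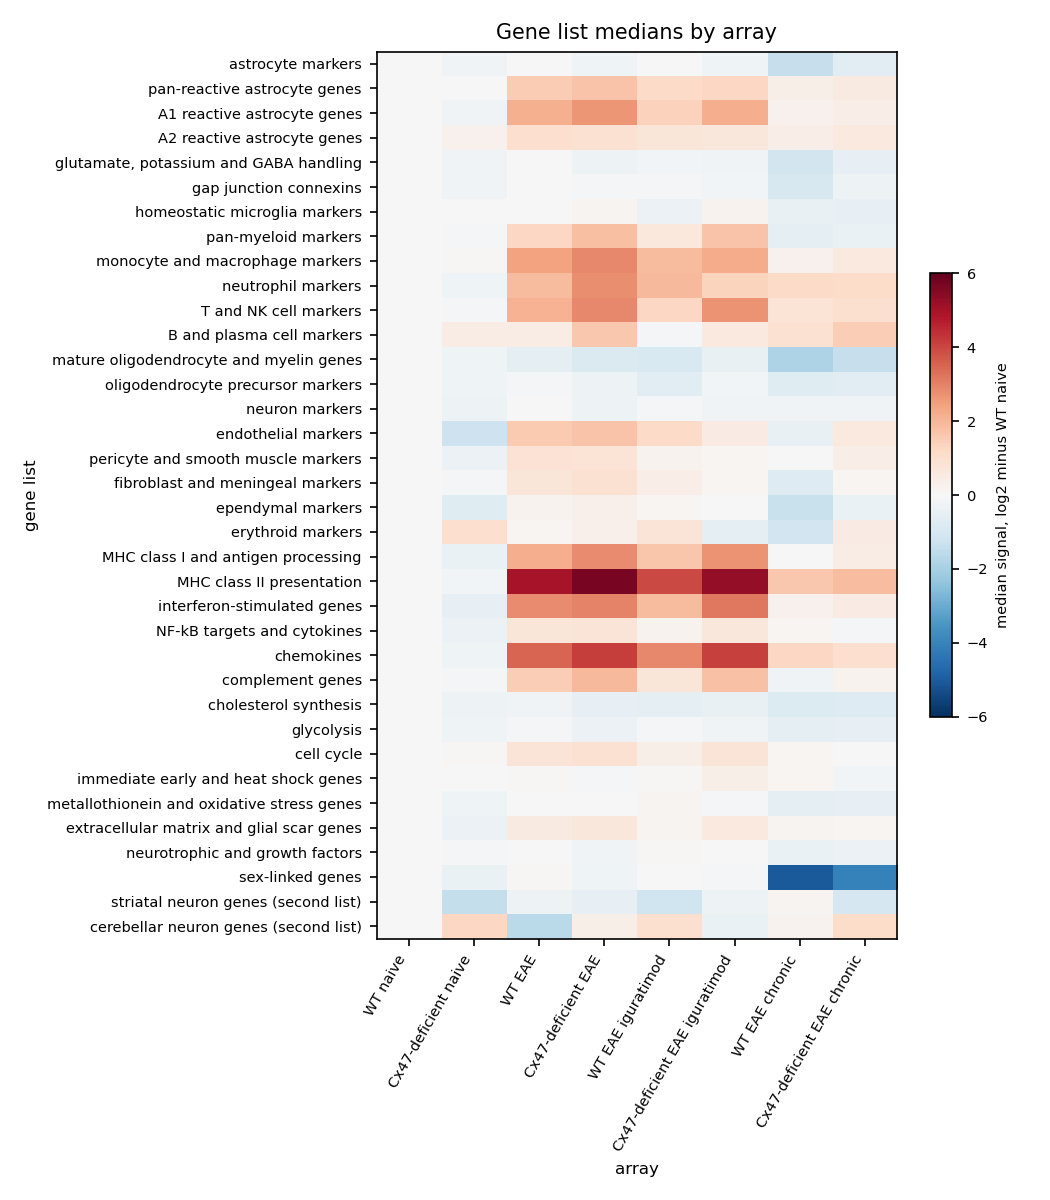
Median signal of each gene list, as log2 minus the WT naive array (colour scale), with lists on the vertical axis and the 8 arrays on the horizontal axis. MHC class II presentation and chemokines were the reddest lists on each of the EAE and iguratimod arrays, and sex-linked genes the bluest on the chronic arrays.

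Whether iguratimod altered the EAE profile was asked against untreated EAE. Over both genotypes inflammatory genes lay lower with iguratimod: Il1a, dim on both iguratimod arrays, by at least 1.18-fold, Lcn2 by a log2 difference of -1.18 ± 0.50, Tgm1 by -0.996 ± 0.21, C3 by -0.94 ± 0.30, Timp1 by -0.93 ± 0.21, Cxcl10 by -0.93 ± 0.20, S1pr3 by -0.86 ± 0.18, Cd74 by -0.81 ± 0.35 and the proliferation gene Top2a by -0.80 ± 0.28. None passed the test. Gfap differed by -0.51 ± 0.22, Gja1 by -0.23 ± 0.26 and Il6, well above background on 1 of 2 arrays of each group, by -0.94 ± 0.81. Gjb6 differed by 0.03 ± 0.28, and its sign turned under normexp, quantile normalization and the authors' values (each -0.01), without WT EAE (-0.03) and without WT iguratimod (-0.21). Limma called 0 genes. At an unadjusted p under 0.05 there were 543, of which 139 were higher and 404 lower, against 1294 that chance would give. Genotype differences that vary between conditions are part of the spread in the fit. A count under that of chance therefore does not show that iguratimod had no effect. Camera called 20 lists lower and 1 higher, and fry called 0. The pan-reactive astrocyte list had a median of -0.69, with 0 of 12 members above 0 and 3 lower when adjusted over the list alone (camera adjusted p 5.54e-11; adjusted p = 0.210 with an estimated correlation). Complement genes had a median of -0.65 (camera adjusted p 1.37e-07; adjusted p = 0.383 with an estimated correlation) and endothelial genes -0.77 (camera adjusted p 5.7e-06; adjusted p = 0.390 with an estimated correlation). Markers of infiltrating cells lay lower too. Monocyte and macrophage genes had a median of -0.53, with 0 of 13 above 0 (camera adjusted p 0.000125; adjusted p = 0.383 with an estimated correlation), and neutrophil genes -0.55, with 0 of 11 above 0 (camera adjusted p 0.000462; adjusted p = 0.390 with an estimated correlation). T and NK cell genes had a median of -0.49, with 1 of 13 above 0 (camera adjusted p 0.00312; adjusted p = 0.579 with an estimated correlation), and B and plasma cell genes -0.66, with 0 of 6 above 0 (camera adjusted p 0.000824; adjusted p = 0.383 with an estimated correlation). Immediate early and heat shock genes had a median of 0.17 (camera adjusted p 0.00132; adjusted p = 0.390 with an estimated correlation). No list call held with an estimated correlation, and slide 1 alone gave 21 camera calls.

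On the WT arrays, inflammatory genes were lower with iguratimod and cerebellar neuron genes higher. Il1b differed by -1.49, Cxcl10, Ifi44 and Mx1 by -1.20 each, C4b by -1.17, Cd2 by -1.15, Serpina3n by -1.14, Cd74 by -1.08 and Gfap by -0.66. The T and NK cell list had a median of -0.89, interferon-stimulated genes -0.75, MHC class I -0.69, MHC class II -0.97 and chemokines -0.87, each below all matched random lists (percentile 0), while the neutrophil list was at 0.05 (percentile 62.8). Myeloid lists were lower too. As log2 minus WT naive, pan-myeloid markers went from 1.24 in EAE to 0.62 with iguratimod, and monocyte and macrophage markers from 2.41 to 1.90. Gabra6 and Cbln3, genes of cerebellar granule neurons, were higher by 3.81 and 3.57, as were Sycp1 (4.01), Bcl2l15 (3.81), Cpsf4l (3.64) and Chil5 (3.60). The striatal genes Adora2a (-2.41), Drd1 (-2.25), Gpr6 (-2.20) and Rgs9 (-1.90) were lower, with Serpina9 (-1.92) and Ido1 (-1.82). Gja1 differed by -0.03 and Gjb6 by 0.26, and Il6 was not well above background on either array. In all, 699 genes were higher and 277 lower by 2-fold, or 71.6% higher, and under normexp 236 and 31, or 88.4% higher.

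On the Cx47-deficient arrays, neutrophil, vessel and reactive astrocyte genes were lower with iguratimod and immediate early and heat shock genes higher, without a test. Lcn2 differed by -1.79, the neutrophil genes Mpo and Ngp by -1.73 and -1.63, Slco1a4 by -1.40, Timp1 by -0.96 and C3 by -0.85. The neutrophil list had a median of -1.26, the endothelial list -0.91 and pan-reactive astrocyte genes -0.66, all at percentile 0. Interferon-stimulated genes were at 0.10 (percentile 95.3), T and NK cells at -0.07 (percentile 56.2) and MHC class I at -0.10 (percentile 1.45). Immediate early and heat shock genes had a median of 0.61, with 12 of 13 above 0 (percentile 100), against -0.05 in WT (percentile 30.3). The immediate early genes Nr4a1 (1.24), Arc (1.16) and Egr2 (1.09) were among the largest on the higher side, with Cox8b (1.54), Nkx2-9 (1.33) and Rhcg (1.27). Ssty1 (-3.12), Dsg1c (-2.96), C78197 (-2.96), Duox2 (-2.90) and AK214641 (-2.87) were lower, and Vmn1r197 was at least 8.59-fold lower. Gfap differed by -0.36, Gja1 by -0.44 and Gjb6 by -0.19. Il6 differed by -0.02, and its sign turned under normexp (0.11), quantile normalization (0.27), median centring (0.01) and the authors' values (0.26). In all, 64 genes were higher and 830 lower by 2-fold, or 7.16% higher; the counts were 172 and 526 under quantile normalization, or 24.6% higher, and 23.9% were higher with the authors' values.

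The comparison of iguratimod with EAE in a genotype shares its EAE array with the comparison of EAE with naive. To avoid that, genes 2-fold higher in EAE in the other genotype were followed. The 1197 such genes of the Cx47-deficient arrays had a median iguratimod difference of -0.57 in WT, with 91.1% lower against 49.7% of all genes. The 748 such genes of the WT arrays had a median of -0.22 in the Cx47-deficient mice, with 76.7% lower against 49.5% of all genes. Both medians lay below all matched random lists (percentile 0), and the difference between the genotypes was not tested.

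Chronic EAE was compared with naive, on arrays of another slide, to see what remained late in disease. Myelin genes lay lower on the chronic arrays, and Mog, a myelin surface protein, fell by 2.24 on the log2 scale (SE 0.26, adjusted p 0.0455). Adjusted over the list alone, 15 of 16 myelin genes fell and 1 rose (camera adjusted p 7.86e-08; adjusted p = 0.726 with an estimated correlation). Mbp was at -2.47 ± 0.32 and Mobp at -2.25 ± 0.33, neither past the test over all genes. Astrocyte markers had a median of -0.81, with 0 of 20 above 0 and 9 lower when adjusted over the list alone (camera adjusted p 4.89e-06; adjusted p = 0.726 with an estimated correlation). Gfap was at -1.12 ± 0.22 (adjusted p 0.0700), Gja1 at -0.98 ± 0.26 and Gjb6 at -0.72 ± 0.28. Of the 5 Gja1 probes, 2 lay the other way, at 0.98 and 1.70. Il6 was well above background on 1 of 2 chronic arrays and on neither naive array, so no fold is given. Of the chemokines, Cxcl10 rose 3.999-fold (well above background on 1 of 2 naive arrays), and 6 of 16 rose when adjusted over the list alone (camera adjusted p 0.00168; adjusted p = 0.726 with an estimated correlation). Cholesterol synthesis genes had a median of -0.58 (camera adjusted p 0.000509; adjusted p = 0.726 with an estimated correlation). Lower medians were thus not particular to myelin and astrocyte genes. As log2 minus WT naive, glycolysis genes were at -0.57 on the WT and -0.49 on the Cx47-deficient chronic array. Metallothionein and oxidative stress genes were at -0.56 and -0.49 on these arrays. T and NK cell genes lay the other way, at 0.81 and 0.98.

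The largest changes were in sex-linked genes. The X-inactivation transcript rose at least 277-fold under the probe named XIST and at least 8.46-fold under the probe named Xist, while the Y-linked genes Eif2s3y, Ddx3y and Uty fell at least 55.4-fold, 9.90-fold and 7.95-fold, being dim on both chronic arrays. The Y-linked gene Kdm5d, named after its values were seen, was well above background on all 8 arrays, at -0.53 ± 0.18 (adjusted p 0.125). Eif2s3x, the X-linked partner of Eif2s3y, fell by 2.81. Other rises were at least 54.7-fold for Ms4a15, 10.1-fold for Adamts19, 9.26-fold for Col24a1, 3.54-fold for Crybg1 and 2.94-fold for Tfap2c, each dim on both naive arrays, and 9.26-fold for BB097682. The calcium-binding gene Cabp7 fell by 2.57 and Rs5-8s1 by 2.86; AK029817 fell at least 36.5-fold and BX528370 at least 13.9-fold. Sex, slide and phase of disease cannot be told apart in any comparison with the chronic arrays.

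In all, limma called 241 genes in chronic EAE against naive, 181 higher and 60 lower (75.1% higher), of which 16, or 6.64%, lay on X or Y, against 3.93% of the genes tested. Camera called 7 lists lower and 1 higher, fry called 2, and no call held with an estimated correlation. The count was 3873 under normexp (54.8% higher), 19 under quantile normalization (57.9% higher), 12 with the authors' values (41.7% higher), and between 1 and 3 when any of the 8 arrays was left out. In the single genotypes 4225 genes were higher and 2471 lower by 2-fold in WT, and 2206 higher and 577 lower in the Cx47-deficient mice, without a test.

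Chronic EAE was also compared with EAE. Of the 64 genes that rose in EAE, 60 fell, but the shared EAE arrays alone would lower genes chosen in this way. In a comparison without shared arrays, chosen after the result was seen, genes 2-fold higher in EAE in one genotype were followed from EAE to chronic EAE in the other. The 1216 such genes of the Cx47-deficient arrays had a median of -1.30 in WT, with 85.7% lower against 51.2% of all genes. The 749 such genes of the WT arrays had a median of -1.64 in the Cx47-deficient mice, with 91.7% lower against 45.7% of all genes. Both medians lay below all matched random lists (percentile 0). Of the 64 genes, the other 4, named after their values were seen, did not pass the test: Ms4a15 (-0.36 ± 0.34, adjusted p 0.458), Crybg1 (-1.33), Pdcd1 (-0.73) and Scgn (-1.31). Cxcl10 fell by 4.90 on the log2 scale (SE 0.20, adjusted p 0.00769), Cxcl9 by 4.92, Cfb by 4.95 and the acute phase gene Saa3 by 5.08. Of 17 interferon-stimulated genes 13 fell, and 14 when adjusted over the list alone (camera adjusted p 4.71e-07; adjusted p = 0.384 with an estimated correlation). Of 11 MHC class I genes 8 fell and of 7 MHC class II genes 6, among them H2-Aa by 3.99, and 11 and 7 when adjusted over the list alone (camera adjusted p 4.71e-07 and 1.76e-05; for both lists adjusted p = 0.384 with an estimated correlation). Of 12 pan-reactive astrocyte genes 7 fell, including Lcn2 by 4.08, Serpina3n by 3.35 and Gfap by 2.70 (adjusted p 0.0233), and 9 when adjusted over the list alone (camera adjusted p 9e-07; adjusted p = 0.384 with an estimated correlation). Of 20 astrocyte markers 4 fell, among them Gja1 by 1.15, Fabp7 by 1.76 and the potassium channel Kcnj10 by 1.35, and 8 when adjusted over the list alone (camera adjusted p 9.76e-06; adjusted p = 0.414 with an estimated correlation). Of 13 monocyte and macrophage genes 8 fell, with Lyz2 falling by 2.90, and 11 when adjusted over the list alone (camera adjusted p 1.6e-06; adjusted p = 0.384 with an estimated correlation). The fall of Gja1 is that of its brightest probe; of its 5 probes, 2 lay higher in chronic EAE, at 1.80 and 2.45. Mbp fell by 1.96 and Mog by 1.40.

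Fewer named genes rose from EAE to chronic EAE. The growth factor Fgf2 rose by 2.33 ± 0.26 (adjusted p 0.0286; 1 of 2 EAE arrays well above background) and the B cell gene Ms4a1 by 3.18 ± 0.67 (adjusted p 0.0442). Acot12 rose at least 3.81-fold, Defb14 8.60-fold, CF617398 10.6-fold and AK035359 3.33-fold, each dim on both EAE arrays; Tssk5 rose 33.9-fold, and Tmem52b 17.5-fold with 1 of 2 EAE arrays well above background. The probes named XIST and Xist rose at least 298-fold and 9.11-fold, and Eif2s3y, Ddx3y, AK029817 and BX528370 fell at least 55.3-fold, 8.63-fold, 13.4-fold and 11.9-fold. Gjb6 was at -0.73 ± 0.28 and Il6, well above background on 1 of 2 arrays of each group, at -0.65 ± 0.81, neither past the test, and without the Cx47-deficient chronic array Il6 was at 0.42.

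In all, limma called 3810 genes, 2411 higher and 1399 lower (63.3% higher), with 3643 and 3635 under normexp (50.1% higher), 2100 and 2176 under quantile normalization (49.1% higher) and 2057 and 2136 with the authors' values (49.1% higher). Camera called 27 lists lower and none higher, and fry called 17; no call held with an estimated correlation. Leaving out WT EAE, Cx47-deficient EAE or WT chronic left 1 call each, leaving out Cx47-deficient chronic 1168, leaving out either iguratimod array 675 and leaving out either naive array 2646.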

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

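The tests of the iguratimod pattern below were chosen only after the result was seen. In 6 cases the median of a gene list moved one way on the WT arrays and the opposite way on the Cx47-deficient arrays, each in the outer 5% of matched random lists; with 1 array per group these differences were not tested. Striatal neuron genes from EAE against naive were at -0.30 in WT and 0.95 in Cx47-deficient mice (difference -1.25). From iguratimod against EAE, myelin genes were at -0.31 and 0.41 (-0.72), neuron markers at -0.22 and 0.23 (-0.45), and erythroid markers at 0.74 and -0.89 (1.63). In the same comparison striatal neuron genes were at -0.94 and 0.24 (-1.19), and cerebellar neuron genes at 2.41 and -0.76 (3.18).

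Interferon-stimulated genes were lower after iguratimod on the WT arrays (-0.75) and not on the Cx47-deficient arrays (0.10). A lower share of every infiltrating cell type alike is argued against by neutrophil markers at 0.0501 in WT. The bootstrap interval of -0.16 to 0.16 resampled the 11 neutrophil markers of 1 pair of arrays and does not measure the spread between samples. The normalization is argued against by a median of -0.66 or lower in WT under both quantile normalization and normexp. A lower share of T cells may account for it, with T and NK cell markers at -0.89 in WT, a hypothesis found and tested on the same arrays. T cells are not the only candidate. As log2 minus WT naive, pan-myeloid markers went from 1.24 in EAE to 0.62 with iguratimod in WT, and monocyte and macrophage markers from 2.41 to 1.90. In Cx47-deficient mice they went from 1.81 to 1.71 and from 2.87 to 2.21. A lower share of myeloid cells was not tested. A response to iguratimod that depends on genotype could not be told apart from the spread between single arrays (difference -0.84).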

How the results depend on the processing

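The use of slide 1 alone for counts of called lists was chosen only after the result was seen; the other alternatives were planned. Pairing by replicate number was not possible, because each group has 1 array and no replicate numbers link animals. The fit itself pairs the genotypes within condition. A lone array was assumed to vary like the other groups. At an unadjusted p under 0.05 genotype gave 1143 genes, 232 with no condition block and 1098 with condition as a random block. Genotype and iguratimod gave 0 genes in limma under every alternative run, and camera's list counts stayed within 1.5 times. Values of named genes were tallied together with those of the later striatal and cerebellar neuron lists. The tally also took in 2-fold counts of EAE or chronic EAE against naive within a genotype. Over all alternatives 2720 of these values kept direction and side of the threshold, 797 kept direction only, 104 moved, 1 newly passed and 29 reversed. Of values of the lists fixed beforehand, 1426 kept both, 50 kept direction only, 30 moved and 1 reversed. Signal over background limits the dim genes. Probes well above background on fewer than 2 of the 8 arrays were left out. A fold against a group dim on all its arrays is a lower bound, while a gene dim on some arrays of a group has its fitted value, which includes the dim signal.

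Counts that moved by over 1.5 times were as follows, in the order EAE against naive, chronic against naive, chronic against EAE where given. Under normexp with quantile normalization they were 231, 3873 and 7278; under quantile normalization 38 and 19; with the authors' values 38 and 12; with no filter 15, 25 and 1049; with genes well above background on all arrays 206 and 1806; with trended and robust moderation 307, 1961 and 6408; with no genotype block 106 and 889. EAE against naive gave 108 under median centring and 0 on slide 1 alone. Leaving out each array gave 0 to 0 for genotype and for iguratimod, 0 to 11 for EAE against naive, 1 to 3 for chronic against naive and 1 to 2646 for chronic against EAE. The 2-fold counts in the naive, EAE, iguratimod and chronic genotype pairs and in iguratimod against EAE in WT and in Cx47-deficient mice were 876, 363, 301, 165, 267 and 160 under normexp, and 742, 504, 203, 172, 298 and 253 at 3-fold. Among genes well above background on all arrays the last 5 were 1038, 662, 350, 610 and 345. The fewer arrays lower the counts when arrays are left out, and a higher threshold lowers the 3-fold counts; otherwise the cause was not tested.

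Signs that turned were, for Gjb6 in the iguratimod fit, -0.01 under normexp (-0.0089), quantile normalization (-0.014) and the authors' values (-0.014), -0.03 without WT EAE and -0.21 without WT iguratimod. For Gjb6 in the EAE pair they were 0.051, 0.0696 and 0.0699 under the same 3 settings and 0.0898 with the mean of probes. For Il6 after iguratimod in Cx47-deficient mice they were 0.11, 0.27 and 0.26, and 0.01 (0.0071) under median centring, which also turned Gja1 for genotype (-0.0101), Gfap in the EAE pair (-0.01) and astrocyte markers after iguratimod in Cx47-deficient mice (0.0042). The mean of probes turned Gja1 (-0.19) and Gjb6 (-0.11) in EAE, Tyms in chronic against EAE (0.0443), and Gja1 in the naive (0.31) and iguratimod (0.33) pairs. Without Cx47-deficient naive, Gja1 and Gjb6 in EAE were at -0.01 (-0.0089) and -0.20; without Cx47-deficient EAE, Gjb6 was at -0.05. Without either iguratimod array Il6 for genotype was at -0.39; without either chronic array, and on slide 1 alone, Gja1 for genotype was at -0.15; without Cx47-deficient chronic, Il6 in chronic against EAE was at 0.42. The highest values on leaving out an array were 0.14 for Gja1 and 0.79 for Il6 in the genotype fit, 0.36 for Gja1 and 0.23 for Gjb6 in EAE against naive, and 0.27 for Gjb6 in the iguratimod fit; the lowest for Il6 in chronic against EAE was -1.72. The cause was not tested.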

Other observations

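Of the tests below, the splits of the arrays, the share of neurons, and all tests of the higher differences in the naive and EAE pairs were chosen only after the result was seen. The Hox genes were also chosen after their values were seen: of 33 kept, 23 were well above background on all 8 arrays. The first component of all genes held 64.8% of the variance, and both chronic arrays lay at its positive end (133 and 114); the second held 13.5%.

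No gene passed the test of the genotype effect, and with 0 genes for the real split any other split gives at least as many (32 of the 32 splits of the 8 arrays into 4 and 4 that could be fitted, the real one included), so this count decides nothing about chance. The highest other gave 627. That count came from 2 splits that, with condition in the fit, are the same comparison: WT against Cx47-deficient in the naive and EAE pairs, with the iguratimod and the chronic pairs not parted. A structure of the samples may lie behind that count. Since that comparison follows genotype, a genotype difference in those conditions stays open as well, and neither was tested. At an unadjusted p under 0.05 the real split gave 1143 genes, at rank 16, and the median of the others was 1124. Many of the other splits also repeat one another and part the genotypes in only some conditions. The rank and the median are thus over unlike comparisons and decide nothing.

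Striatal and cerebellar neuron genes were among the largest differences in the naive pair. Second lists of such genes, other genes on the same arrays, moved apart there: cerebellar genes were at 1.23 and striatal genes at -1.44, a gap of 2.67, and all members were well above background on all 8 arrays. In the other genotype pairs the cerebellar and striatal medians were 1.98 and -0.25 in EAE, -1.31 and 0.99 with iguratimod, and 0.76 and -1.08 in chronic EAE, beside the differences in immune and glial genes there. A different share of neurons as the whole cause is argued against by general neuron markers at -0.29, against regional lists that moved apart by 2.67. The bootstrap interval of -0.41 to -0.08 resampled the 14 neuron markers of this pair of arrays. It lies below 0 and does not measure the spread between samples. The normalization is argued against by a gap of 2.60 under quantile normalization. A different mix of brain regions in the starting tissue may account for it, as a hypothesis, although the tissue label is spinal cord and how the cells were isolated was not given in the sources used here. No biological explanation was tested.

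In the naive and EAE genotype pairs most 2-fold differences were higher (75.2% and 90.6%). Among genes well above background on all arrays the shares were 71.9% and 89.5%, so the pattern was not confined to genes dim on some array. Median differences did fall with signal, from the dimmest to the brightest of 6 bins of probes. For cDNA and tag probes they went from 0.80 to -0.10 in the naive and 0.68 to -0.13 in the EAE pair. For RefSeq mRNA probes they went from 0.21 to -0.20 and from 0.30 to -0.17. A difference between slides cannot enter the shares of these pairs, whatever their size, since both arrays of each pair lay on slide 1. Whether the normalization made the share of higher differences stays open: it was 54.0% in the naive and 68.1% in the EAE pair under quantile normalization, but 73.2% and 91.5% under normexp with quantile normalization. Within this pattern, cDNA and tag probes exceeded RefSeq mRNA probes of like signal by 0.61 in the naive and 0.41 in the EAE pair, against 0.07 in the iguratimod and -0.08 in the chronic pair, and the 0.585 left under quantile normalization in the naive pair (0.21 under normexp) argues against the normalization as the whole cause of that excess. More RNA of unannotated or unspliced sequence in some preparations may account for the excess, as a hypothesis, and no biological explanation was tested.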
